A study of Homo sapiens with 16 samples.

How the data were processed

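Gene expression was measured in HEK293 cells, a human embryonic kidney cell line. Per the labels' protocols the cells received 5 µM Senexin A, an inhibitor of the Mediator kinases CDK8 and CDK19, or 0.1% DMSO as vehicle for 1 h, and then TNF-α at 10 ng/mL or no TNF for 2, 6, 12 or 24 h. The 16 samples form 16 groups of treatment and time, with 1 sample in each. They were hybridised in pairs to 8 2-colour Agilent arrays with 62976 spots each. The vehicle sample of an array carried Cy3 and the Senexin A sample Cy5 throughout, with no dye swap. The file headers place all 8 arrays on 1 slide and in 1 scan, so no slide or scan batch divides the groups. TNF and no-TNF arrays, and early and late arrays, had fixed positions on the slide, so position cannot be told apart from treatment and time.

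Per the file headers the scans were read by Agilent Feature Extraction 10.7.3.1, the version that the submitters' processing notes also name. The deposited spot files hold intensity values: the median brightness of each spot and of its local background, a processed intensity that the scanner software background-subtracted and dye-normalized, and flags for spots well above background, saturated or uneven. The 2 files of an array were identical in 8 of 8 cases, and each sample was read from the channel its label names. The deposited series matrix holds log2 values for 42545 probes, controls included, as the values show, centred on each probe's median over the 16 samples. Its column medians were 0.00759 and 0.00881 for vehicle and Senexin A at 3 h, 0.00847 and 0.0141 at 7 h, -0.000425 and -0.00773 at 13 h, and -0.00344 and -0.00782 at 25 h. With TNF they were -0.000282 and -0.00277 at 2 h, 0.0152 and 0.0108 at 6 h, 0.00446 and -0.00271 at 12 h, and -0.00294 and -0.0130 at 24 h. All columns had a mean of 0.0391. Against log2 processed intensity centred the same way, over probes well above background in all 16 samples, the columns had correlations of 0.957 to 0.988 and slopes of 0.924 to 0.985. The direction and scale are thereby known, and the exact normalization behind the matrix is not given in the sources used here.

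The spot files carry median and no mean spot signals, so the median signals were used where mean signals had been planned. Background was corrected with normexp (offset 50), channels were normalized by loess within arrays and by Aquantile between arrays, control spots had no weight and 0.507% of spot readings flagged as outliers were left out. Spots of a probe were averaged, and the brightest probe represented a gene. A probe had to be well above background in at least 2 of 16 samples. The spot files give accessions, and 26364 of 42405 probes matched a symbol through the RefSeq gene table (assembly GRCh38.p14). The array files name another build, so no coordinates are printed. This left 21595 features, 14784 with a symbol and 6811 without; 3604 of the named genes had several probes. Features without a symbol were tested and counted but not named, and 1 gene that the naming rule picked is not reported here.

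Between 50.6% and 58.5% of probes were well above background. Median spot brightness was 82.5 to 109 in Cy3 and 317 to 392.5 in Cy5, over local backgrounds of 55 to 71 and 142 to 154. No Cy3 spot was saturated and 4 to 40 Cy5 spots were. The number of arrays limits the precision.

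7 comparisons were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on log2 values, with Benjamini-Hochberg adjustment at 0.05. The TNF effect was the difference between samples with and without TNF of the same dye and time. The change of the TNF effect by Senexin A was the TNF effect with Senexin A minus that with vehicle. The Senexin A over vehicle ratio was taken within arrays, without and with TNF, and its slope on log2 exposure time was fitted over all 8 arrays with TNF as a covariate (5 residual degrees of freedom), which treats the 2 arrays of a time as independent. The TNF effect averaged over both pretreatments was fitted on log2 TNF time. The 4 time points stand in for replicates, so limma p-values measure the spread between time points, which includes real change with time. Nothing shows the spread between cultures. A constant dye bias of a gene cancels in all but the Senexin A over vehicle ratios, where it cannot be told apart from the inhibitor. A dye-dependent range of fold changes does not cancel in the change of the TNF effect.

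The test design, 23 gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. The rule takes, per fit, the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05 and the same sign at all time points (no sign condition for slopes), or, where fewer than 5 pass, the 5 largest each way with 1 sign throughout, given as values. Per time point it takes the 8 largest rises and 5 largest falls of the mean TNF effect. It adds up to 6 members of a list and a fixed set of cytokine, NF-kB, Mediator kinase and reference genes. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. TNF-responsive genes were tested with an exact sign-flip test over 4 time points, whose smallest two-sided p is 0.125.

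A probe not well above background in any sample of an arm has only a bound there. Its fold is given as "at least", the bright arm's mean against the dim arm at the higher of its own value and the lowest signal among probes well above background in that sample; between dyes such bounds are open to dye bias.

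The tests were tried on simulated data with 200 changed genes among 21595. The noise was drawn from variances that limma had already moderated, and the number of changed genes was set, so the rates hold for that setting. For the TNF effect with vehicle, 57 of 67 genes changed by 0.5 (log2) and 67 of 67 changed by 1 were called, and 20 unchanged genes, 9.52% of calls, were called too. For the change by Senexin A, 65 of 67 genes changed by 0.5 were called, with 12 unchanged genes (5.71% of calls). In the data *CXCL2*, with a change of -1.18, did not pass (limma, adjusted p = 0.62), so this rate is no guide to what was missed. Unchanged genes made up 9.39% of calls for the TNF effect with Senexin A, and 7.87% and 7.83% for the Senexin A over vehicle ratio without and with TNF. For the Senexin A slope, 2 of 67 genes with a slope of 0.1, 46 of 67 with 0.2 and 66 of 66 with 0.4 were called, with 6 unchanged genes. For the TNF slope, 3 of 67 genes with a slope of 0.2 and 64 of 66 with 0.4 were called, and 14 unchanged genes made up 17.3% of calls. Alternatives covered the background correction, normalization, filter, probe rule, values of the series matrix, variance model, a separate-channel fit (intraspot correlation 0.249), single time points left out, and thresholds.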

Results

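The data are 16 expression profiles of HEK293 cells, 4 time points for each of 4 treatments: vehicle, Senexin A, vehicle with TNF and Senexin A with TNF. Senexin A was given at 5 µM from 1 h before TNF (10 ng/mL), so that TNF times of 2, 6, 12 and 24 h match total exposures of 3, 7, 13 and 25 h. The comparisons ask what TNF, a cytokine that activates the transcription factor NF-kB, changed in these cells, what inhibition of CDK8 and CDK19 changed, and whether the inhibitor altered the response to TNF. Changes are log2 values with the standard error of limma over n = 4 time points, or over 8 arrays (2 per time) for the slope of the Senexin A over vehicle ratio. No time point has a replicate.

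TNF with vehicle pretreatment raised genes of the NF-kB response at all 4 time points. *RELB*, an NF-kB subunit, rose by 3.82 ± 0.19 (adjusted p = 0.00017), *IER3*, a stress-response gene, by 3.44 ± 0.13 (adjusted p = 4.6e-05), and *NFKBIA*, the inhibitor of NF-kB, by 3.12 ± 0.11 (adjusted p = 4.6e-05). *CXCL1*, a neutrophil chemokine, had the highest value, 4.80 ± 0.35 (adjusted p = 0.00116), with 2 of 4 vehicle samples well above background. The monocyte chemokine *CCL2* rose by 2.73, the chemokine *CXCL2* by 2.38, the proteoglycan *SDC4* by 2.31 and the NF-kB inhibitor *TNFAIP3* by 2.30. *TNF* rose at least 5.02-fold and *TNFRSF9*, a TNF receptor family member, at least 4.67-fold, since neither was well above background in any vehicle sample. In all, 55 genes rose, 51 of them named, and 8 fell out of 21595 tested. The 8 that fell were *RIMBP3* (-0.72), *OLIG1* (-0.64), *FZD4* (-0.55), *CITED2* (-0.55), *RAB3A* (-0.55), *PAG1* (-0.55), *ZNF503* (-0.54) and *KCTD12* (-0.52). The number that fell was 0 without 6 h, 12 h or 24 h, with offset 16 and with the series matrix, 1 with the processed intensities or the mean of a gene's probes, and 26 without 2 h.

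In the NF-kB feedback list 8 of 21 measured genes rose with vehicle pretreatment and 13 did not pass; adjusted over the list alone, 13 rose and 1 fell. Examples are *BIRC3*, an apoptosis inhibitor (2.16 ± 0.10), and *BCL3* (1.70 ± 0.09). The list shifted up (camera, adjusted p = 3.6e-28, and adjusted p = 0.0236 with an estimated correlation). Of the 17 measured cytokine and chemokine genes 8 rose, and adjusted over the list alone 11 did (camera, adjusted p = 6.5e-20, and adjusted p = 0.0236 with an estimated correlation). *CXCL10* rose at least 3.57-fold, *CCL20* at least 2.20-fold and *CXCL8*, the neutrophil chemokine IL-8, at least 1.59-fold. *IL32* had a value of 2.19 ± 0.44 and did not pass (adjusted p = 0.154). *IL6* had 1 probe, well above background in 0 samples, and was not tested. In the adhesion, matrix and antigen presentation list 5 of 25 rose, and 13 adjusted over the list alone. They were *SDC4*, *CD83* (2.20 ± 0.11), *IRF1* (1.21 ± 0.08), *TAPBP* and *PLAU* (1.03 ± 0.12). *ICAM1*, a leukocyte adhesion molecule, did not pass (adjusted p = 0.163); it was well above background in 1 of 4 samples with TNF and 0 of 4 without. The shift of this list (adjusted p = 4.1e-17) had an adjusted p = 0.136 with an estimated correlation. Of 33 immediate early genes *JUNB* rose (1.15 ± 0.08, with 2 of 4 vehicle samples well above background), and 6 rose adjusted over the list alone (camera, adjusted p = 5.6e-07, and adjusted p = 0.0671 with an estimated correlation); *EGR1* stood at 0.19 ± 0.08 (adjusted p = 0.591).

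With Senexin A pretreatment TNF raised 71 genes and lowered 12. *RELB* rose by 3.96 ± 0.21, *IER3* by 2.96 ± 0.07, *CXCL1* by 2.75 ± 0.24, *NFKBIA* by 2.70 ± 0.07 and *DEPP1*, a FOXO-regulated autophagy gene, by 2.49 ± 0.11 (adjusted p from 2.4e-06 to 0.00336). *TNFAIP3* (2.31 ± 0.08), *BCL3* (2.12 ± 0.12) and *BIRC3* (2.04 ± 0.10) rose too, *TNFRSF9* at least 4.51-fold and *TNF* at least 4.29-fold. *RIMBP3* (-0.78), *OLIG1* (-0.71), *ZNF503* (-0.70), *PHACTR3* (-0.65), *RAB3A* (-0.61), *FGF9* (-0.58), *CITED2* (-0.58), *PLPP3* (-0.57), *TRIB1* (-0.56) and *IQCJ-SCHIP1* (-0.50) fell. The number that fell was 0 without 12 h or 24 h and with the processed intensities, 1 with the series matrix, 2 without 6 h, 4 with offset 16 or median centring and 80 without 2 h. Of the NF-kB feedback list 9 of 21 rose, 15 adjusted over the list alone, and of the cytokines and chemokines 6 of 17 rose, 11 adjusted over the list alone with 1 that fell. Both shifts passed with a preset correlation (adjusted p = 4.1e-31 and 6.5e-16) and an estimated one (adjusted p = 0.0337 for both). The adhesion list's shift (5 of 25 rose, 12 adjusted over the list alone, adjusted p = 1.6e-15) had an adjusted p = 0.157 with an estimated correlation, as did that of the immediate early list (1 of 33 rose, 7 adjusted over the list alone, adjusted p = 7.0e-06).

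The 55 and 71 risen genes of the 2 pretreatments shared 47, where independent lists would share 0.181, and the 8 and 12 fallen shared 5 (0.00445). The 2 lists come from different samples on the same arrays. Both counts moved with the processing. Genes that passed numbered 178 and 276 with probes well above background in at least 8 samples, 178 and 278 with the separate-channel fit and 137 and 149 with a trended, robust variance, but 14 and 18 with the series matrix values and 15 and 15 with the processed intensities. Without the 2 h point 152 and 301 passed, without 6 h 22 and 26, without 12 h 23 and 20, and without 24 h 29 and 28.

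**Figure D1:**
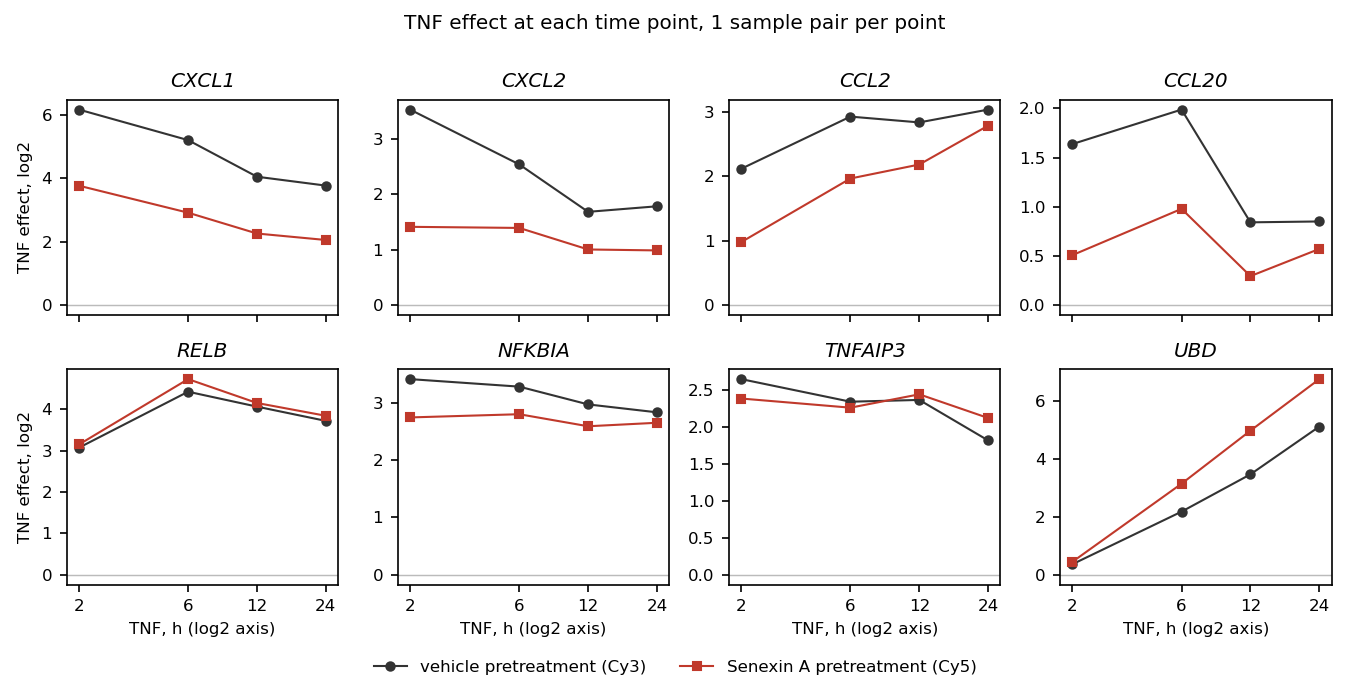
TNF effect (log2, y axis) against hours of TNF (log2 x axis) for 8 genes, with vehicle (circles) or Senexin A (squares) pretreatment; each point is 1 sample pair. For *CXCL1* the Senexin A line lies below the vehicle line at all 4 times (-2.40 at 2 h and -1.72 at 24 h), while the *RELB* lines differ by at most 0.30.

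The change of the TNF effect by Senexin A passed for 1 gene. The *CXCL1* effect was 2.05 ± 0.12 lower with Senexin A (change -2.05, adjusted p = 0.00669), at 4 of 4 time points: -2.40 at 2 h, -2.29 at 6 h, -1.79 at 12 h and -1.72 at 24 h. Without TNF, 2 of 4 samples were well above background with vehicle and 2 of 4 with Senexin A. The next lowest changes did not pass (adjusted p = 0.62 each): *CXCL2* (-1.18 ± 0.21), *CCL2* (-0.75 ± 0.13), *CCL20* (-0.74 ± 0.14) and *CALCA*, the calcitonin gene (-0.66 ± 0.10). *CXCL8* was at -0.62 ± 0.06 (adjusted p = 0.111), and was not well above background in any sample with Senexin A and TNF. The highest values, none of which passed, were *UBD*, a ubiquitin-like modifier (1.05 ± 0.23), *PTGES* (0.55 ± 0.12), *DEPP1* (0.53 ± 0.09), *CRIM1-DT* (0.45 ± 0.10) and *LOC100240734* (0.43 ± 0.11). The NF-kB regulators *RELB* (0.15 ± 0.06), *BIRC3* (-0.13 ± 0.06), *TNFAIP3* (0.01 ± 0.09), *NFKBIA* (-0.43) and *IER3* (-0.48) did not pass either, nor did *TNF* (-0.28), *ICAM1* (0.30) and *EGR1* (-0.05). Some passed in 1 alternative setting each (limma). These were *TNFAIP3* (adjusted p = 0.0230, highest value 0.94), *CALCA* (adjusted p = 0.0220), *NFKBIA* and *DEPP1* (adjusted p = 0.0497 each). *UBD*, *PTGES*, *CCL20*, *CXCL8*, *TNF* and *ICAM1* were not well above background in any sample without TNF, so their changes compare effects that are only bounds.

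In the cytokine and chemokine list *CXCL1* passed over all genes, and adjusted over the list alone 7 genes fell and 1 rose of 17. The list shifted down (camera, adjusted p = 3.9e-05), which was lost with an estimated correlation (adjusted p = 0.821); its mean was -0.34 and its median -0.07. Under median centring its mean was 0.107 (adjusted p = 0.698), and the changes of *TNF* and *BIRC3* were 0.82 and 0.50. *CXCL2*, *CCL2*, *CCL20* and *CXCL8* had negative changes, and did not pass, in each setting that measured them. Of the NF-kB feedback list's 21 genes 0 passed over all genes, and 1 rose and 2 fell adjusted over the list alone (median 0.06, adjusted p = 0.203). At an unadjusted p under 0.05 limma counted 1432 genes for this comparison, against 1080 by chance. *CXCL1* missed the threshold with the processed intensities (-1.96, adjusted p = 0.37), the smaller offset (-2.05, adjusted p = 0.0923), the series matrix (-1.87, adjusted p = 0.405), the separate-channel fit (adjusted p = 0.694) and without the 6 h point; across alternatives its adjusted p ran from 3.8e-07 to 0.694 and its value from -2.16 to -0.93. The vehicle effect is a Cy3 and the Senexin A effect a Cy5 measurement.

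Genes with a mean TNF effect of at least 1 at a time point (149, 129, 69 and 79 genes at 2, 6, 12 and 24 h) had median changes by Senexin A of -0.12, -0.07, 0.13 and 0.13. Their mean was 0.01 (exact sign-flip test over 4 time points, two-sided p = 0.75; 4 time points are too few for this test to pass). The early and late medians have opposite signs here. Without genes seen on 1 array alone (67, 76, 67 and 75 genes left) the medians were -0.11, 0.06, 0.14 and 0.13, so the sign at 6 h turned. The mean was -0.236 with the series matrix and 0.577 with median centring, in both cases with 1 sign at all 4 time points. Picked at the other 3 time points, the medians were -0.01, 0.11, 0.10 and 0.01 (exact p = 0.375).

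At single time points the order of TNF genes differed (no test, 1 sample per group). Averaged over pretreatments, *CXCL1* was highest at 2 h (4.97), with *IER3* (3.47), *RELB* (3.11) and *NFKBIA* (3.08) also in the top 8. At 6 h *RELB* (4.57), *CXCL1* (4.06), *IER3* (3.1), *NFKBIA* (3.04) and *UBD* (2.66) were in it. At 12 h it held *UBD* (4.22), *RELB* (4.10), *CALCA* (3.44), *CXCL1* (3.16), *IER3* (3.13), the cytokine *IL32* (3.01), *TNFRSF9* (2.88) and *NFKBIA* (2.78). At 24 h it held *UBD* (5.94), *CALCA* (4.74), *IL32* (3.84), *RELB* (3.78), *TNF* (3.34), *IER3* (3.12), *CXCL1* (2.92) and *CCL2* (2.91). The other 2 h entries were *ADGRF3*, *SLC38A11*, *OR8B12* and *RBMY2EP*, each well above background on 1 array alone. The other 6 h entries were *NAP1L5* and *NLRP10*, likewise seen on 1 array, and *FAM99B*. Of the 5 lowest values at 2 h, *RNF128*, *WFDC5* and *AKAP14* came from probes above background on 1 array alone, unlike *KRTAP19-8* (-3.07) and *LINC00174* (-2.56), and at 6 h all 5 did (*TERB1*, *ZNF69*, *LILRB5*, *FAM240A* and *RFX3*). The lowest at 12 h were *CCDC178* (-1.12), *MYOM2* (-1.07), *SCGB1D2* (-1.03), *TSC22D3* (-0.94) and *OR5H15* (-0.88), and at 24 h *MYOM2* (-1.19), *SCGB1D2* (-0.97), *SIRPG* (-0.96), *SCGB1D1* (-0.91) and *PCARE* (-0.91). *CCDC178*, *OR5H15* and *SIRPG* were above background on 1 array alone. *UBD*, *TNF* and *TNFRSF9* were not well above background in any sample without TNF, so their values depend on the background correction.

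With both pretreatments 121, 103, 55 and 63 genes were at least 2-fold higher at 2, 6, 12 and 24 h, and 122, 105, 3 and 2 at least 2-fold lower; 0 moved in opposite directions. Of the 2 h and 6 h genes 64.2% and 54.3% came from probes above background on 1 array alone, against 3.45% and 3.08% at 12 h and 24 h. Without them the counts were 55, 65, 54 and 61 higher and 32, 30, 2 and 2 lower. Both pretreatments of a time share their arrays, so a spot that is bright on 1 array moves both.

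**Figure D2:**
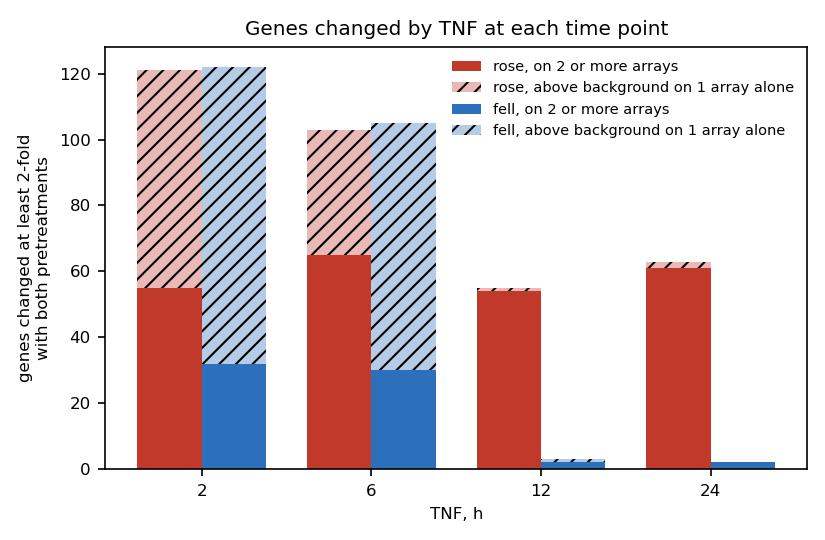
Number of genes at least 2-fold higher (red) or lower (blue) with TNF in both pretreatments, against hours of TNF; hatched parts are genes whose probe was well above background on 1 array alone. At 2 h the hatched parts hold 66 of 121 higher and 90 of 122 lower genes, and at 24 h 2 of 63 and 0 of 2.

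The TNF effect grew with time for 4 genes and shrank for 0 (limma, unadjusted p under 0.05 for 1353 genes). Per doubling of TNF time, *UBD* gained 1.54 ± 0.05 (adjusted p = 0.00036), *CALCA* 1.20 ± 0.05, *IL32* 0.94 ± 0.05 and *COL7A1*, a type VII collagen, 0.63 ± 0.05 (adjusted p = 0.025). *EGFL6* (0.62), *CXCL1* (-0.60), *H2AB2* (-0.57), *RSPO3* (-0.51), *ARHGAP30* (-0.48) and *MYOM2* (-0.34) did not pass. *UBD* and *EGFL6* were not well above background in any sample without TNF, and *H2AB2* was above it on 1 array alone. Adhesion, interferon, p53 and TGF-beta lists shifted up with the preset correlation (adjusted p from 5.3e-06 to 3.1e-05) and not with an estimated one (adjusted p = 0.50 each). Adjusted over the list alone 5 adhesion and 4 TGF-beta genes gained, and 0 of the interferon and p53 lists. The fit has 2 residual degrees of freedom; with a time point left out it called 41 gains and 8 losses (without 2 h), 224 and 175 (6 h), 5 and 1 (12 h) and 165 and 94 (24 h), with probes well above background in 8 samples 38, and with the processed intensities or series matrix 0.

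Among genes that fell in the ratio of Senexin A over vehicle without TNF, *MYC* (-1.62 ± 0.18, adjusted p = 0.00334) and *JUN* (-1.23 ± 0.11, adjusted p = 0.002) were lowest. The immediate early gene *EGR1* was at -0.90 ± 0.18 (adjusted p = 0.0168). Of 33 measured immediate early genes 13 fell, 0 rose and 20 did not pass, and 16 fell adjusted over the list alone, among them *ARC* (-0.68), *IER2* (-0.51) and *ATF3* (-0.48). *C11orf96* (-1.15), *ZCCHC12* (-1.13), *KCTD12* (-1.03), the heat shock gene *HSPA1B* (-1.03), *ADAMTS1* (-0.97), *NDRG1* (-0.96), *ZNF711* (-0.96) and *DEPP1* (-0.91) fell as well. *LETR1* (1.06), *TSHZ2* (1.01), *PEAR1* (0.93), *ANXA2R-OT1* (0.91) and the ribosomal protein *RPL23* (0.83) rose; the *RPL23* spot was saturated in 3 of 4 Senexin A samples, so its value is not exact. *PAPPA2*, *PLXNC1*, *UCA1* and *GBP5* were at least 1.73-fold, 1.69-fold, 1.80-fold and 1.76-fold higher; their probes were well above background in all 4 Cy5 and 0 of 4 Cy3 samples. *TSHZ2* and *PEAR1* were above background in 1 of 4 Cy3 samples. In all 2088 genes rose and 1442 fell, 56 and 35 of them at least 1.5-fold. Without the 3 h array 1864 genes passed, without 7 h 976, without 13 h 2602 and without 25 h 702.

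With TNF 2085 rose and 1383 fell, but with the processed intensities 553 rose and 801 fell. Without 2 h 2311 genes passed, without 6 h 1403, without 12 h 1218 and without 24 h 1609. The lowest ratios were *CXCL1* (-2.19 ± 0.13), *MYC* (-1.78 ± 0.13), *JUN* (-1.49 ± 0.09), *ZCCHC12* (-1.35), *C11orf96* (-1.24), *CXCL2* (-1.17), *ZNF711* (-1.08), *NDRG1* (-1.08), *ADAMTS1* (-0.96) and *EGR1* (-0.95). The highest were *LETR1* (0.97), *ANXA2R-OT1* (0.85), *STRA6* (0.81), *LGALS1* (0.80), *ACTA2* (0.80), *GPR155* (0.80), *RPL13A* (0.79), *PLXNC1* (at least 1.69-fold) and *DNAI4* (at least 1.71-fold, with 0 of 4 Cy3 samples well above background). *CXCL8* was at least 1.65-fold lower.

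Both ratios shared list shifts. The immediate early list shifted down without TNF (adjusted p = 4.2e-07) and with TNF (adjusted p = 7.0e-07), and with an estimated correlation neither passed (adjusted p = 0.304 and 0.411). With TNF 13 of its genes fell and 1 rose, and 13 fell and 2 rose adjusted over the list alone. Under median centring its mean with TNF was 0.0348, where the median of all genes was 0.46. In the TGF-beta and BMP target list 4 of 11 genes fell and 0 rose without TNF, with 6 that fell adjusted over the list alone (adjusted p = 0.00033, and adjusted p = 0.321 with an estimated correlation), with the BMP-induced inhibitors *ID1* (-0.52) and *ID2* (-0.55). Of 30 ribosomal protein genes 25 rose without and 23 with TNF (medians 0.40 and 0.37), or 26 and 27 adjusted over the list alone, with adjusted p = 0.304 and 0.411 with an estimated correlation. The reference genes *ACTB* (0.51 ± 0.06) and *GAPDH* (0.24 ± 0.05) also passed. *CDK8* (0.07 ± 0.07) and *CDK19* (0.08 ± 0.05) did not pass, and of the 7 genes of the Mediator kinase module 0 passed without TNF and *MED12* rose with it (0.26 ± 0.07), with 2 that rose adjusted over the list alone. Of 17 cytokine and chemokine genes 2 rose and 6 fell with TNF, and 2 rose and 8 fell adjusted over the list alone (camera, adjusted p = 0.00326, and adjusted p = 0.667 with an estimated correlation). Senexin A was always Cy5, so a dye bias of a gene cannot be told apart from the inhibitor in these ratios. With median centring in place of loess 18129 and 18337 genes passed, and with the series matrix 672 and 152.

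The slope of the Senexin A over vehicle ratio on exposure time is free of a constant dye bias. Per doubling of time 142 genes gained and 30 lost over the 8 arrays. With the 2 arrays of a time averaged, so that 4 values remain, limma called 0 genes (unadjusted p under 0.05 for 2482), and the genes named here had adjusted p from 0.173 to 0.285. *TSC22D3*, a glucocorticoid-induced gene, gained 0.57 ± 0.07 (adjusted p = 0.0214), *INPP5D* 0.46, *TRIB1* 0.41 ± 0.03 (adjusted p = 0.00213), the apolipoprotein *APOE* 0.38, *FOXQ1* 0.36, *DEPP1* 0.35, *MYC* 0.34 ± 0.06, *SPEN-AS1* 0.33, *RAB26* 0.33 and *SPEN* 0.32. The *TSC22D3* ratio went from -0.55 at 3 h to 0.98 at 25 h without TNF and from -0.71 to 1.23 with it. *ZCCHC12* (-0.44), *NKAIN1* (-0.28), the stress regulator *ATF4* (-0.25), *STC2* (-0.23), the transferrin receptor *TFRC* (-0.22), *GAL* (-0.20), *ZBTB17* (-0.20), *QRSL1* (-0.20), *HSPD1* (-0.20) and the amino acid transporter *SLC7A5* (-0.20) lost.

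Of 28 targets of p53, 7 gained over all genes and 21 did not pass, and 16 gained and 1 lost adjusted over the list alone. They include *BTG2* (0.29), *BAX* (0.26), *TP53I3* (0.26) and *TP53INP1* (0.21). The list's shift passed at either correlation over the 8 arrays (adjusted p = 5.7e-14, and adjusted p = 0.00677 with an estimated correlation). On the averages per time it passed with the preset correlation (adjusted p = 1.6e-13) and not with an estimated one (adjusted p = 0.293). All 27 measured G2 and M phase genes had a negative slope, 1 of which (*AURKA*, -0.19) passed, and 13 adjusted over the list alone; the shift (adjusted p = 2.7e-12) had an adjusted p = 0.248 with an estimated correlation. Of 29 ATF4 and unfolded protein response genes 3 lost and 0 gained, and 6 lost and 1 gained adjusted over the list alone (adjusted p = 4.8e-05, and adjusted p = 0.41 with an estimated correlation). The interferon response list had 0 of 28 genes that passed and 8 that gained adjusted over the list alone (adjusted p = 0.0001, and adjusted p = 0.213 with an estimated correlation). Early and late arrays lay in different columns of the slide. The count of 172 was not stable: it was 0 without the 3 h or 25 h arrays, 1 without 7 h and 19 without 13 h. It was 4 with offset 16 or without a filter, 1 with the processed intensities or series matrix, 408 with probes well above background in 8 samples, 431 without background correction, 929 with median centring and 1231 with a trended, robust variance.

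**Figure D3:**
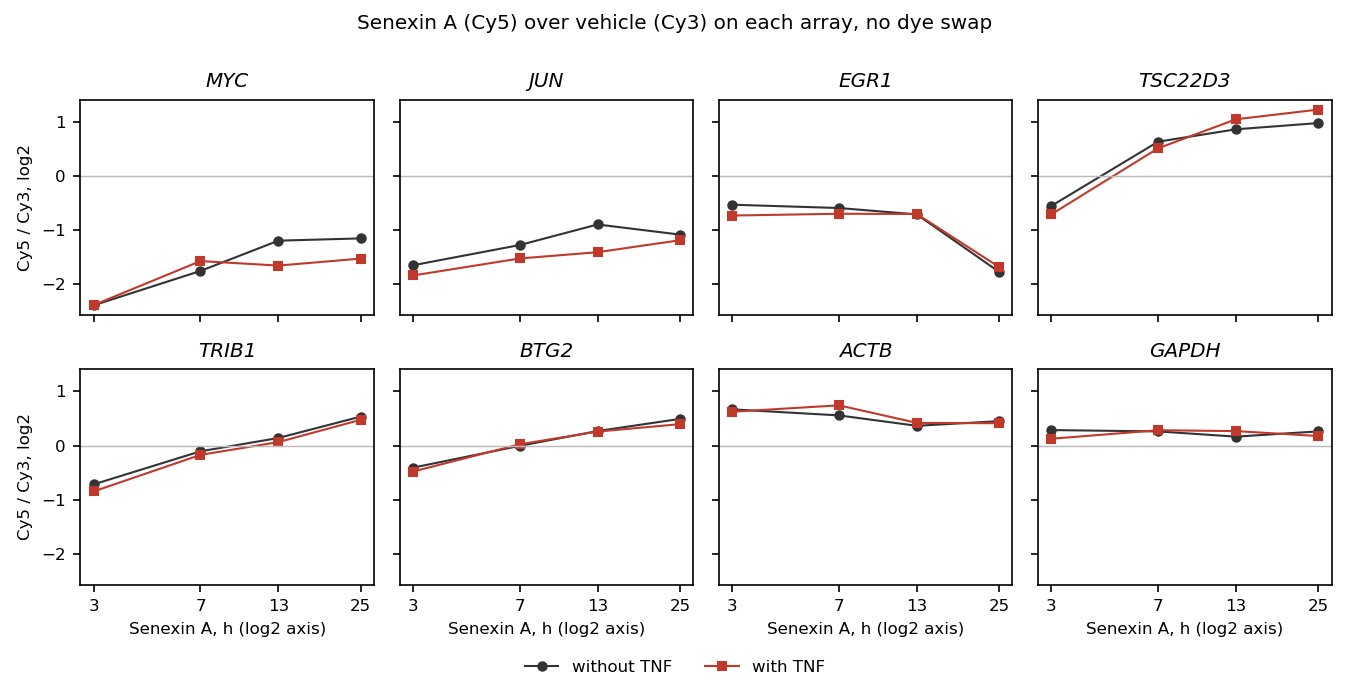
Log2 ratio of Senexin A (Cy5) over vehicle (Cy3) on each array (y axis) against hours of Senexin A (log2 x axis), without TNF (circles) and with TNF (squares), for 8 genes; each point is 1 array. *TSC22D3*, *TRIB1* and *BTG2* climb from below 0 at 3 h to above 0 at 25 h, *MYC* and *JUN* stay below 0, and *ACTB* and *GAPDH* stay above 0 at all 4 times.

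Of 12 leukocyte markers 6 and of 12 fibroblast and endothelial markers 3 were measured, and 0 of either list passed in either TNF effect. In the Senexin A over vehicle ratios without and with TNF 1 of 6 and 1 of 3 rose.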

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

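The tests on chemokines, dye bias and spots seen on 1 array were chosen after the results were seen; the splits of samples, the orders of time points and the test for clustered spots were set beforehand, and how far they can exclude chance was judged again afterwards. *CXCL1* is listed here because its TNF effect differed between the pretreatments (-2.05, adjusted p = 0.00669). *UBD* (1.54), *CALCA* (1.20), *IL32* (0.94) and *COL7A1* (0.63) are listed because their TNF effect differed between time points, by the slope per doubling of time. The Senexin A over vehicle ratio of 142 genes rose and of 30 genes fell with time, again by the slope.

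Other groupings of the samples were counted for each comparison. For the TNF effects, the 8 splits of the 8 samples that part all 4 pairs of a time are too few: the real one called 63 genes with vehicle (highest other 0) and 83 with Senexin A (0). The 24 splits that part fewer pairs carry less of the difference and called at most 1 and 0; 3 further splits of each could not be fitted. Orders of the time points are too few as well, since an order and its reverse ask for nearly the same trend. The real order called 4 genes for the TNF slope (highest other of 24 orders 0) and 172 for the Senexin A slope, where the reverse called 211 and the remaining orders 0. The 8 sign assignments over 4 time points are too few for the other comparisons: the real one gave 1 gene for the change of the TNF effect (highest other 0), 3530 without TNF (0) and 3468 with TNF (0), in each case 1 of 8.

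The first pattern is the smaller TNF induction of chemokines with Senexin A. A narrower range of the Cy5 channel, as large as *CXCL1* would need, is argued against by 11 strongly induced genes outside the cytokine list, which kept a median of 0.941 (SD 0.19) of their log2 effect where *CXCL1* kept 0.573. These are loess-normalized values, and under median centring the *CXCL1* change was -0.93. *CXCL1* was well above background in 12 of 16 samples, against 16 for *RELB*, *IER3* and *NFKBIA*. A loss of range near the background is therefore not tested. A smaller loss of range stays open for the other chemokines, since 43 induced genes went both ways (median change 0.0792, SD 0.31). Of these 43 genes, 13 had a negative change. *IER3* (-0.48), *NFKBIA* (-0.43), *SDC4* (-0.42), *CD83* (-0.39), *CALCA* (-0.66) and *EGFL6* (-0.19) were lower at 4 of 4 times. Others were higher at 4 of 4 times, among them *DEPP1* (0.53), *BCL3* (0.42), *COL7A1* (0.37), *LGALS1* (0.36) and *DDR1* (0.30). The 10 spike-in RNAs had a mean change of -0.23 on processed intensities. Their mean TNF differences were small (0.22 in Cy3 and -0.01 in Cy5), so they do not bear on a loss of range at large effects. An effect of the inhibitor on NF-kB targets in general, as large as on 8 induced cytokines (median -0.64), is argued against by 10 induced NF-kB feedback genes (median 0.10). Of these 10, 3 had a negative change, *IER3* and *NFKBIA* among them, so an effect on some NF-kB targets stays open. Without *CXCL1*, *CXCL2* and *CXCL3* the induced cytokines had a median of -0.28 (SD 0.44), too spread out to set them apart. Cross-hybridization from *CXCL1* to *CXCL2* and *CXCL3* stays open: the 5 cytokine genes other than these that were induced on average over both pretreatments had a median of -0.28, and with *CXCL8*, induced with vehicle alone, the median of 6 was -0.45 (SD 0.41), past the bound of -0.4 by less than the spread.

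The second pattern is the 3530 and 3468 Senexin A over vehicle calls. Among genes with a second probe its sign matched in 77.9% of 584 called genes without TNF and 61.4% of others. The difference of 16.5 percentage points was close to the bound of 15 that was set after similar values had been seen. It argues only against a dye bias private to single probes as the whole cause. Called genes have larger ratios, and both probes bind the same labelled transcript, so a dye bias of the transcript would give it too. For genes whose ratio changed with time, a constant dye bias cancels in the slope by design, so the test on orders of the time points set beforehand (2 of 24 called as many genes) does not bear on it; behaviour of single probes is argued against by the second probe, with the same sign of slope in 92.9% of 28 called and 65.4% of other genes. For the ribosomal proteins the median slope was -0.00713 (SD 0.055) around a constant ratio, as a constant dye bias of abundant short transcripts would give; an early and lasting effect of the inhibitor would look the same. Single genes with a constant ratio stay open to dye bias.

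The third pattern is the large number of 2-fold changes at 2 h and 6 h. Of the 426 genes concerned, 63.1% had a probe above background on 1 array alone, which is what bright spots of single arrays would give. For raised genes a response at 1 time alone would look the same. For lowered genes, of which 90 of 122 at 2 h and 75 of 105 at 6 h were such, it would also need expression without TNF at that time alone. Such spots lay close together: on the 4 early arrays their median nearest distance was 0.193 of that of random spots, as a smear or scratch would leave. Clustering was not particular to early arrays, as the late arrays had 0.110 (25 h without TNF) to 0.636. The early arrays held 113 to 238 such features and the late arrays 33 to 59.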

How the results depend on the processing

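Counts depended strongly on the processing. Of all named gene and list values, 2609 kept side and direction, 465 lost and 49 gained the threshold and 65 turned sign. This tally does not measure how stable directions are. Most named genes were picked for large effects. The filters, the variance model and the separate-channel fit left values such as the *CXCL1* change (-2.05) as they were. Of the values and counts that answer a comparison, 131 were labelled the same, 114 moved and 7 turned sign. A count was the same if it lay within 1.5-fold of the main count. The mean change of TNF-responsive genes was the same if it kept its sign and its side of the threshold, whatever its size. The filter on 2 arrays, the 1.5-fold minimum and the slope on averages per time were chosen after seeing the data; causes were not tested, except that fewer or more features are tested under another filter. Signal over background limits dim genes. In the order TNF effect with vehicle, with Senexin A, its change, Senexin A over vehicle without TNF, with TNF, its slope and the TNF slope, the main counts were 63, 83, 1, 3530, 3468, 172 and 4. Processed intensities gave 15, 15, 0, 1054, 1354, 1 and 0, with 553 rises and 801 falls for the ratio with TNF. The series matrix gave 14, 18, 0, 672, 152, 1 and 0. Offset 16 gave 29, 44, 0, 2137, 2046 and 4 (slope). Median centring gave 54 with Senexin A, 2 for the change, 18129 (13680 rises and 4449 falls), 18337 (13825 and 4512) and 929 (466 and 463), and moved the median of all ratios to 0.39 and 0.46. No background correction gave a slope count of 431, and averages of the 2 arrays of a time 0 (limma, unadjusted p under 0.05 for 2482). No filter gave 2228 without TNF, 4 and 10 for the slopes, and the mean of probes 33 with vehicle. A filter of 8 samples gave 178 (133 and 45), 276 (198 and 78), 408 and 38 (29 and 9), and of 2 arrays 167 (129 and 38), 246 (182 and 64), 389 and 38 (31 and 7). Trended, robust variances gave 137 (97 and 40), 149 (108 and 41), 4 for the change (1 and 3), 1231 (832 and 399) and 20. The separate-channel fit gave 178 (135 and 43), 278 (205 and 73) and 0 for the change. Calls of at least 1.5-fold numbered 91 and 114. Leaving out 1 time point gave 22 to 152, 20 to 301, 0 to 1, 702 to 2602, 1218 to 2311, 0 to 19 and 6 to 399.

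Of 43 list shifts 5 held with an estimated correlation, where camera also has fewer degrees of freedom. Genes raised with both pretreatments at 2, 6, 12 and 24 h numbered 391, 301, 157 and 215 (lowered 383, 367, 1.1e+02 and 82) with processed intensities, 411, 324, 180 and 216 (386, 364, 66 and 72) with the series matrix, and 291, 226, 142 and 161 (290, 271, 42 and 37) at 1.5-fold. Offset 16 gave 198 raised at 2 h and 203, 178, 7 and 12 lowered, median centring 76 raised and 63 lowered at 2 h, and no normalization between arrays 5 lowered at 24 h. The filter of 8 samples gave 39 and 55 raised at 2 and 6 h, and 14, 17 and 1 lowered at 2, 6 and 24 h; that of 2 arrays gave 50 and 57 raised, and 23 and 22 lowered.

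The mean change of TNF-responsive genes (0.01) turned to -0.0694 with processed intensities, -0.0157 without background correction, -0.00353 with the mean of probes, -0.236 with the series matrix and -0.0676 when picked on vehicle alone, and ran from -0.0235 to 0.0601 with a time point left out. This test cannot pass with 4 time points; the series matrix medians were negative at all 4.

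Most other values that turned lay near 0. Processed intensities turned the TNF effect of *GAPDH* with vehicle (-0.00637), the changes of *CDK8* (-0.0408) and *TNFAIP3* (-0.0762), the ratios of *CXCL2* (-0.106) and *ICAM1* (-0.124) without TNF and that of *TNFAIP3* (-0.0187) with TNF. No background correction turned the ratios of *CXCL2* (-0.0213), *TNF* (-0.0114) and *TNFAIP3* (-0.0662) without TNF, and offset 16 the *TNFAIP3* change (-0.0266). Quantile normalization turned that change (-0.00385) and the *CXCL2* ratio without TNF (-0.00447). No normalization between arrays turned the vehicle TNF effects of *CDK19* (-0.0228), *CDK8* (-0.0221) and *GAPDH* (-0.0330), and that of *CDK8* with Senexin A (-0.0140). The mean of probes turned the *CDK8* change (-0.0239). The series matrix turned the *ACTB* effect with Senexin A (0.0141), the changes of *CDK8* (-0.0366) and *TNFAIP3* (-0.0172), the ratios of *CCL20* (0.0150) and *CXCL2* (-0.128) without TNF and that of *TNFAIP3* (-0.0112) with TNF.

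Median centring turned the most signs, some of them past the threshold. In the TNF effects these were *CDK19* (-0.0276), *CDK8* (-0.00338) and *GAPDH* (-0.0309) with vehicle, and *ACTB* (0.0256) and *GAPDH* (0.0413) with Senexin A. Among the changes they were *BIRC3* (0.503), *EGR1* (0.0378), *GAPDH* (0.0722), *TNF* (0.817) and the cytokine list (mean 0.107). Ratios without TNF were *CXCL2* (-0.208), *ICAM1* (-0.746), *IER3* (0.474), *TNF* (-0.661) and *TNFAIP3* (-0.384), all 5 past the threshold. Ratios with TNF were *BIRC3* (0.541) and *NFKBIA* (0.614), past the threshold, *IER3* (0.202), *TNF* (0.157) and the immediate early list (mean 0.0348).

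With 1 time point left out, these ranges held both signs. TNF effects with vehicle ran from -0.103 to 0.00757 for *ACTB*, -0.0638 to 0.138 for *CDK19*, -0.0354 to 0.102 for *CDK8* and -0.0388 to 0.0506 for *GAPDH*. With Senexin A they ran from -0.102 to 0.135 for *CDK8* and -0.0282 to 0.0126 for *GAPDH*. Changes ran from -0.0102 to 0.0668 for *ACTB*, -0.138 to 0.171 for *CDK8*, -0.0748 to 0.0125 for *GAPDH* and -0.0893 to 0.0998 for *TNFAIP3*. Ratios without TNF ran from -0.0695 to 0.0254 for *CCL20*, -0.0204 to 0.0801 for *CXCL2* and -0.0660 to 0.119 for *TNF*, and with TNF from -0.0618 to 0.0346 for *BIRC3*, -0.108 to 0.240 for *CDK8* and -0.0474 to 0.117 for *TNFAIP3*. The TNF slopes ran from -0.856 to 0.0341 for *H2AB2* and -0.791 to 0.0520 for *RSPO3*.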

Other observations

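The tests in this part were chosen after the values they build on were seen. Cholesterol synthesis genes moved both ways in the Senexin A over vehicle ratio with TNF: 7 of 25 rose and 4 fell (8 and 6 adjusted over the list alone; camera, adjusted p = 0.682), with the enzymes *IDI1* at -0.84 ± 0.09 (adjusted p = 0.00116) and *HMGCS1* at -0.59 ± 0.08 (adjusted p = 0.0048). In the heat shock list 3 of 15 genes fell and 1 rose without TNF, as adjusted over the list alone, with the near-identical copies *HSPA1A* at -0.75 ± 0.13 and *HSPA1B* at -1.03 ± 0.12. These values share the dye limit of that comparison.

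The change of the TNF effect by Senexin A had a median slope of 0.20 per doubling of time (SD 0.12) over 8 induced cytokine genes, against 0.03 (SD 0.10) over 108 other induced genes, of which 71 had a positive slope. A hypothesis that the inhibitor's effect on them may shrink would need a negative change with a positive slope, as 7 of 8 genes had. *IL32* moved away from 0 (change 0.26, slope 0.03), and *CXCL10* had a change near 0 (-0.06). From 2 h to 24 h the *CXCL1* TNF effect itself fell, from 6.17 to 3.77 with vehicle and from 3.77 to 2.06 with Senexin A. A smaller difference between the pretreatments therefore need not be a smaller share of the effect. *CCL20* and *TNF* were not well above background in any sample without TNF, so their changes compare bounds. Over all genes 0 passed in a limma fit of the slope of the change (unadjusted p under 0.05 for 833, against 1080 by chance). No single gene therefore shows a shrinking effect.

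A second hypothesis, that genes with a late build-up of TNF induction may be induced more with Senexin A, as the *UBD* values hint, was left undecided. Across 116 TNF-induced genes, which are not independent replicates, the slope with time and the change by Senexin A had a Spearman's rho of 0.26 (Pearson's r 0.35).

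The 10 spike-in RNAs, on processed intensities scaled to the 75th percentile, had a mean TNF difference of 0.22 in Cy3 and -0.01 in Cy5, and a mean change by Senexin A of -0.23 (SD 0.07 over 10 RNAs and 4 times). Whether the cells also make RNA that binds the spike-in probes was not tested. Over all genes the median change under this scaling was -0.0105. The scaling sets the 75th percentile of each sample to the same value and so removes a shift that all genes share. This median therefore cannot show whether the genes shared the shift. The changes of *TNF* (-0.28) and the cytokine list (mean -0.34) are on loess-normalized values, so the spike-ins set no error size for them. Both turned positive under median centring (0.817 and 0.107).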
